A study of Mus musculus with 8 samples.

How the data were processed

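Polyadenylated RNA of dendritic cells (DCs) was measured by bulk MARS-seq, a 3′ sequencing method in which each captured molecule carries a unique molecular identifier (UMI). Per the labels, the cells came from popliteal lymph nodes of chimeric C57BL/6 mice and were sorted on CD45, CD11c and MHC-II. The mice were 16 weeks old, 8 weeks after the transplant named in the labels, and had received no treatment (resting) or 10 µg of an antibody against CD40 into the footpad (activated). Chimeras are labelled WT/WT or ICAM-1/2 DKO/WT, and the corresponding libraries are called WT and DKO here. The labels put 8 libraries into 4 groups of 2, and replicate numbers only name libraries.

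Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, cutadapt 1.8.3, TopHat2, HTSeq and DESeq2, and the genome build was mm10. The annotation, the strand setting and the rule for collapsing UMIs are not given in the sources used here. The authors deposited a single table of 10412 genes. Per the file headers, 8 of its columns hold raw UMI counts per gene, which were the input of every test here. Its normalized counts, a signal that is never negative, were made by the authors, and 100% of them equalled the UMI count divided by a median-of-ratios size factor within a relative tolerance of 1e-6. The authors also deposited log2 fold changes and adjusted p-values for 4 comparisons, named in the file headers. They are quoted only as the authors' values, with the sign turned to DKO over WT. A further 8 per-sample columns, on a transformed scale per the file headers, were not used. Every gene in the deposited table had a UMI count of 6 or more in some library, so genes below that level were not analysed here.

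Total UMI counts ran from 401984 to 1294777 per library, with 9801 to 10369 genes detected. A count of 3 UMIs, taken as the floor, corresponds to 2.11 CPM in the deepest library and 7.16 CPM in the library with the highest floor. Intervals and floors cover counting error only. Between the libraries of a group the chi-square per degree of freedom against counting noise was 2.33 to 2.86, which does not tell technical from biological spread, and each library was counted as a sample. Spearman correlations across genes within these pairs were 0.902 to 0.946.

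Genes were filtered with edgeR's filterByExpr by group, which left 8616 tested and 1796 untested genes. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with a coefficient for each group over all 8 libraries, which leaves 4 residual degrees of freedom. Contrasts were tested with the quasi-likelihood F test and adjusted by Benjamini-Hochberg, and "called" means an adjusted p under 0.05. The standard error of a log2 fold change (SE) is its size divided by the square root of F. CPM values are TMM-scaled, with the SD over the 2 libraries of a group. The contrasts were activation (activated minus resting) in WT, in DKO and as the mean of both, genotype (DKO minus WT) at rest, after activation and as the mean of both, and the interaction. Nothing in the labels says whether the libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical. The labels name no batches.

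Of 31 gene lists, fixed like the contrasts and the main test before the data were examined, 29 had 5 or more tested members. They cover functions, DC subsets, other cell types, sample quality and the neighbourhoods of Icam1 and Icam2. Each was tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists. An estimated correlation was also tried, and fry, which asks whether the genes of a list move on balance one way, was added after seeing the data. With the estimated correlation 0 of the 29 lists were called in every contrast, so losing a call there does not single out a list. The markers of erythrocytes and platelets and of granulocytes and mast cells had too few tested members.

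Named genes follow a rule fixed at the same stage. It takes Icam1 and Icam2 in every comparison. In the activation and genotype means it takes the 6 largest called changes in each direction with a mean log2 CPM of 5 or more and the same sign in both strata. It further takes up to 3 called members of each list by p, or the most abundant member if none was called. In the other contrasts it takes the 5 called genes with the smallest p, and in the genotype contrasts adhesion molecules with a mean log2 CPM of 5 or more. Genes outside the rule are said to be so.

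Alternatives chosen at that stage were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter beyond a summed count of 1, a filter of 10 CPM in 2 libraries, limma-voom with quality weights, fits on only the 4 libraries compared, and leaving out each library in turn. The genes tested were held fixed when libraries were left out. Fits without both libraries of lowest depth were added after seeing the data. Simulated counts with 200 changed genes were drawn from the means and library sizes of the real libraries. At a 2-fold change the quasi-likelihood test recovered 54% of changed genes for activation as the mean of both genotypes and 55% for genotype as the mean of both states. At a 4-fold change it recovered 92% and 91%. For the 2-against-2 contrasts, the share recovered at 2-fold was 44% for activation in WT, 25% for activation in DKO, 27% for genotype at rest and 26% for genotype after activation. The interaction recovered 11% at 2-fold and 55% at 4-fold. In the simulated activation contrast, with genes drawn independently of each other, camera called 5 of 5 moved lists and 0 of 20 unmoved lists. This does not test camera on lists whose members vary together.

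Symbols were matched to GENCODE vM21, on the assembly that mm10 names: 10045 directly, 312 through an older symbol, and 55 not at all. Coordinates are 1-based. Reads of near-identical genes, such as Lyz1 and Lyz2 or the Bcl2a1 family, may have been split or lost in the authors' counting, and values for these genes are uncertain.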

Results

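The data are UMI counts of sorted lymph node DCs from WT and DKO chimeras, at rest or after injection of an antibody against CD40, a receptor of the TNF receptor family on antigen-presenting cells. Each of the 4 groups had 2 libraries. WT resting libraries held 1294777 and 711254 UMIs, DKO resting libraries 401984 and 760053, WT activated libraries 822287 and 914623, and DKO activated libraries 803034 and 471235. The design asks how the transcriptome of these cells changes on activation, and whether loss of ICAM-1 and ICAM-2, ligands of the integrin LFA-1, alters it.

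Icam1 (ENSMUSG00000037405.8, mm10 chromosome 9, 21015985 to 21028817) was low in each DKO library. It stood at 168 and 123 CPM in WT resting libraries and at 9.49 and 13.6 CPM in DKO resting libraries. After activation it stood at 407 and 432 CPM in WT and at 38.5 and 35.8 CPM in DKO. The genotype difference was −3.53 ± 0.21 (log2, SE) with an edgeR adjusted p of 3.00e-13. Icam1 rose with activation by 1.51 ± 0.22 in WT (adjusted p = 8.65e-06) and by 1.62 ± 0.42 in DKO (adjusted p = 0.00825). The call in DKO ended without DKO resting replicate 1 (1.42), without DKO activated replicate 1 (1.55), without both libraries of lowest depth (1.48), in a fit of only the 4 libraries compared and in limma-voom, with adjusted p from 0.00897 to 0.103 over 15 alternatives. Icam2 (ENSMUSG00000001029.15, mm10 chromosome 11, 106377656 to 106388075) did not differ detectably between genotypes, at 0.06 ± 0.19 (adjusted p = 0.995). It was at 209 ± 14.1 CPM (SD, n = 2) in WT resting and 182 ± 67.2 CPM in DKO resting libraries. The deleted part of Icam2 is not given in the sources used here, and a 3′ tag outside it checks nothing. Icam2 fell with activation by 1.37 ± 0.26 in WT (adjusted p = 3.06e-04) and stood at −0.79 ± 0.27 in DKO (adjusted p = 0.0458). The DKO call was lost in 11 of 15 alternatives (−1.17 to −0.30, adjusted p from 0.00918 to 0.615), among them the fits without any single library other than DKO resting replicate 2.

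**Figure D1:**
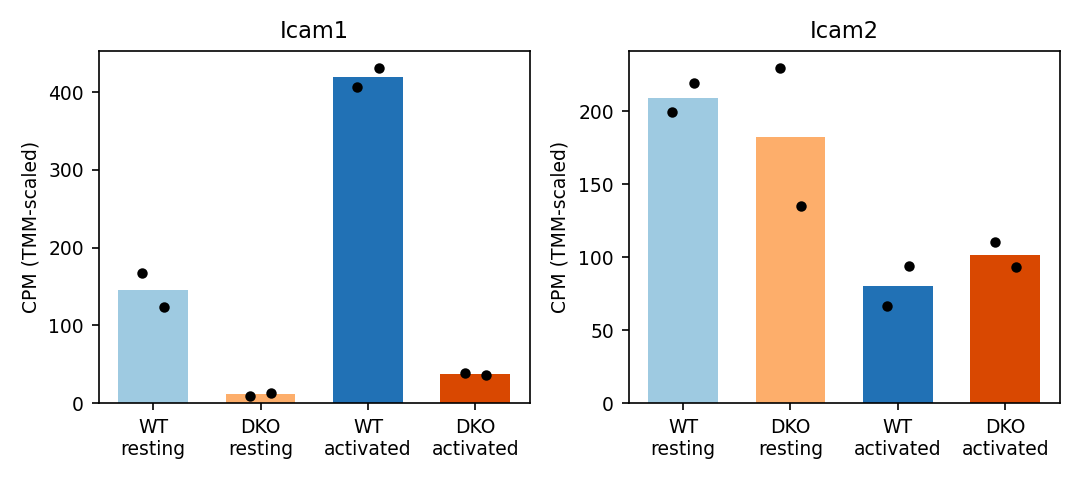
Icam1 and Icam2 transcript levels (y axes, TMM-scaled CPM, linear from 0) in the 4 groups (x axes). Bars are means of 2 libraries and dots are single libraries; Icam1 is at 38.5 CPM or less in each DKO library and at 123 CPM or more in each WT library, while the Icam2 bars of both genotypes stand close together.

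Transcript levels in the sorted cells differed between activated and resting libraries in both directions. Among genes with a mean log2 CPM of 5 or more and the same sign in both genotypes, the 6 largest called rises were Cfb (complement factor B) at 4.45 ± 0.18, Cxcl10 at 4.35 ± 0.32, Cfp (properdin) at 4.10 ± 0.16, Cxcl9 at 3.87 ± 0.27, Iigp1 (an interferon-inducible GTPase) at 3.84 ± 0.41 and Isg15 (a ubiquitin-like modifier) at 3.71 ± 0.31, all log2 ± SE. Cfp went from 59.1 ± 7.86 to 948 ± 75.0 CPM in WT and from 71.1 ± 23.5 to 1263 ± 89.5 CPM in DKO (SD, n = 2). By the same limits the 6 largest called falls were Cacna1i, which encodes a T-type calcium channel subunit, at −6.14 ± 0.41, Fcgrt (the neonatal Fc receptor) at −3.07 ± 0.32, Neurl3 at −3.07 ± 0.20, Vpreb3 at −3.03 ± 0.20, Mylip at −2.91 ± 0.23 and Fos at −2.72 ± 0.41. Fos, an immediate early gene, varied between WT resting libraries (178 ± 187 CPM, SD, n = 2) and stood at −1.73 without WT resting replicate 1. Cacna1i was at 83.9 ± 14.5 CPM in WT resting libraries and below the floor of 3 UMIs in each activated library, so its fitted fold depends on the prior count. As the mean of both genotypes, 2556 of 8616 genes were called by edgeR, 1402 higher and 1154 lower, and 1045 of them changed at least 2-fold.

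Of 47 tested interferon-stimulated genes, 41 rose and 0 fell, with 41 and 0 adjusted over the list alone and a median log2 change of 1.76. Besides Cxcl9, Cxcl10 and Isg15 they included Irf7 and Usp18. The camera adjusted p was 2.20e-25, against an adjusted p of 0.155 with an estimated correlation. Of 22 genes of MHC class I presentation, 15 rose (16 adjusted over the list alone), among them the immunoproteasome genes Psmb9 at 1.34 ± 0.15 and Psmb10 at 1.13 ± 0.13 and the proteasome activator Psme2 at 1.56 ± 0.17. The camera adjusted p was 5.18e-08, and the adjusted p was 0.155 with an estimated correlation. Of 28 targets of NF-kB and CD40 signalling, 13 rose and 1 fell, with the same counts adjusted over the list alone. Traf1, an adaptor of TNF receptor signalling, rose by 1.81 ± 0.16 and Nfkb2 by 1.17 ± 0.13 (camera adjusted p = 4.00e-04, adjusted p = 0.155 with an estimated correlation). Bcl2a1b stood at 2.27 ± 0.21, but its reads can be shared with its paralogs. Of 23 chemokines and chemokine receptors 13 rose and 4 fell, over all genes and adjusted over the list alone. Ccl22 rose by 2.36 ± 0.16 and Ccl17 by 1.98 ± 0.25, ligands of CCR4, whereas the homing receptor Ccr7 fell by 1.11 ± 0.16 (camera adjusted p = 0.00645, adjusted p = 0.175 with an estimated correlation).

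Other lists, those of DC maturation, MHC class II presentation, costimulation, cytokines and the cytoskeleton, held called genes in both directions and were not called. Of 30 DC maturation genes 9 rose, including Cd40 itself and the actin regulator Marcksl1 at 1.97 ± 0.16, and 4 fell (camera adjusted p = 0.110, but 0.0313 without WT resting replicate 1 and 0.0275 without DKO activated replicate 1). Of 20 MHC class II genes 3 rose and 4 fell, with 5 and 4 adjusted over the list alone. The lysosomal thiol reductase Ifi30 rose by 1.29 ± 0.12 and the cathepsin Ctsb by 1.22 ± 0.16, while H2-Ob, a subunit of the H2-O modulator of peptide loading, fell by 1.33 ± 0.13 (camera adjusted p = 0.667). Of 17 costimulatory and coinhibitory ligands 3 rose and 2 fell (camera adjusted p = 0.837, with a median of −0.07 against a mean of 0.17), with the inhibitory receptor gene Lilrb4a up by 2.76 ± 0.29. Of 15 cytokines 6 rose and 3 fell (camera adjusted p = 0.303). Ebi3, a subunit of IL-27 and IL-35, rose by 1.84 ± 0.23 and Il16 fell by 0.79 ± 0.15. Of 39 genes of actin and cell motility 12 rose and 8 fell (camera adjusted p = 0.306), with Actb up by 1.25 ± 0.12. Adjusted over the list alone these 4 counts were 9 and 4, 3 and 2, 6 and 3, and 13 and 8 for maturation, costimulation, cytokines and actin.

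Lists of metabolism and growth held more called rises than falls, and each of these list calls was lost with an estimated correlation. Of 57 genes of oxidative phosphorylation 46 rose and 0 fell (50 and 0 adjusted over the list alone), with a median of 0.64. Cox6b1 rose by 0.99 ± 0.14 and Atp5j2 by 1.04 ± 0.14. The camera adjusted p was 1.05e-18, and the adjusted p was 0.175 with an estimated correlation. Of 24 proliferation genes 18 rose and 1 fell (20 and 1 adjusted over the list alone). Mcm3, a subunit of the replicative helicase, rose by 1.61 ± 0.21 (camera adjusted p = 2.63e-06, adjusted p = 0.274 with an estimated correlation). Of 23 cholesterol synthesis genes 10 rose and 1 fell (12 and 1 adjusted over the list alone). Mvd rose by 2.00 ± 0.27 and Fdps by 1.40 ± 0.21, while the fatty acid desaturase Scd1 fell by 0.92 ± 0.17 (camera adjusted p = 0.00498, adjusted p = 0.236 with an estimated correlation). Of 16 glycolysis genes 7 rose and 0 fell, over all genes and adjusted over the list alone, with Ldha up by 1.01 ± 0.13 (camera adjusted p = 0.00424, adjusted p = 0.175 with an estimated correlation). Of 19 genes of the unfolded protein response 8 rose and 3 fell (8 and 4 adjusted over the list alone), with the chaperone Hspa5 up by 1.04 ± 0.16 (camera adjusted p = 0.0449, adjusted p = 0.29 with an estimated correlation). That call ended without WT resting replicate 2 (adjusted p = 0.0748), WT activated replicate 1 (0.0522), WT activated replicate 2 (0.0541) or DKO activated replicate 2 (0.0853). Of 27 immediate early and dissociation stress genes, a list of sample quality, 15 fell and 4 rose (17 and 4 adjusted over the list alone). Klf2, a transcription factor of lymphocyte quiescence, fell by 2.60 ± 0.18 and the RNA-binding protein gene Zfp36 stood at −1.73 ± 0.16, while the chaperone Hspe1 rose by 1.31 ± 0.17 (camera adjusted p = 0.00125, adjusted p = 0.155 with an estimated correlation).

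Markers of other cell types moved with activation as well. A changed mix of cells and changed expression within cells can therefore not be told apart in the activation contrasts. Of 20 monocyte and macrophage markers 18 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 2.15. Lyz2 (lysozyme) rose by 2.22 ± 0.13 and the scavenger receptor Marco by 2.74 ± 0.21 (camera adjusted p = 6.40e-16, adjusted p = 0.155 with an estimated correlation). Their summed level went from 2869 ± 267 to 6445 ± 539 CPM in WT and from 3462 ± 40.2 to 15146 ± 2968 CPM in DKO (SD, n = 2). Of 23 pattern and uptake receptors 12 rose and 4 fell (13 and 4 adjusted over the list alone), among them Cd36 at 3.41 ± 0.42 and Tyrobp at 1.25 ± 0.15 (camera adjusted p = 0.00125, adjusted p = 0.155 with an estimated correlation). B cell markers were abundant in each library, at a summed 16302 ± 561 CPM in WT resting, 15084 ± 1.47 CPM in WT activated, 18614 ± 1238 CPM in DKO resting and 13893 ± 949 CPM in DKO activated libraries (SD, n = 2). Of 23 tested members 13 fell and 5 rose (14 and 5 adjusted over the list alone). Vpreb3, a protein of early B cell receptor assembly, led the falls, with Ralgps2 at −1.74 ± 0.16 and Fcrla at −1.50 ± 0.15 (camera adjusted p = 8.12e-06, adjusted p = 0.155 with an estimated correlation). Of 24 T cell markers 9 fell and 1 rose, over all genes and adjusted over the list alone, with Thy1 at −0.87 ± 0.17 (camera adjusted p = 0.00282, adjusted p = 0.446 with an estimated correlation, and 0.0557 without WT activated replicate 1).

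**Figure D2:**
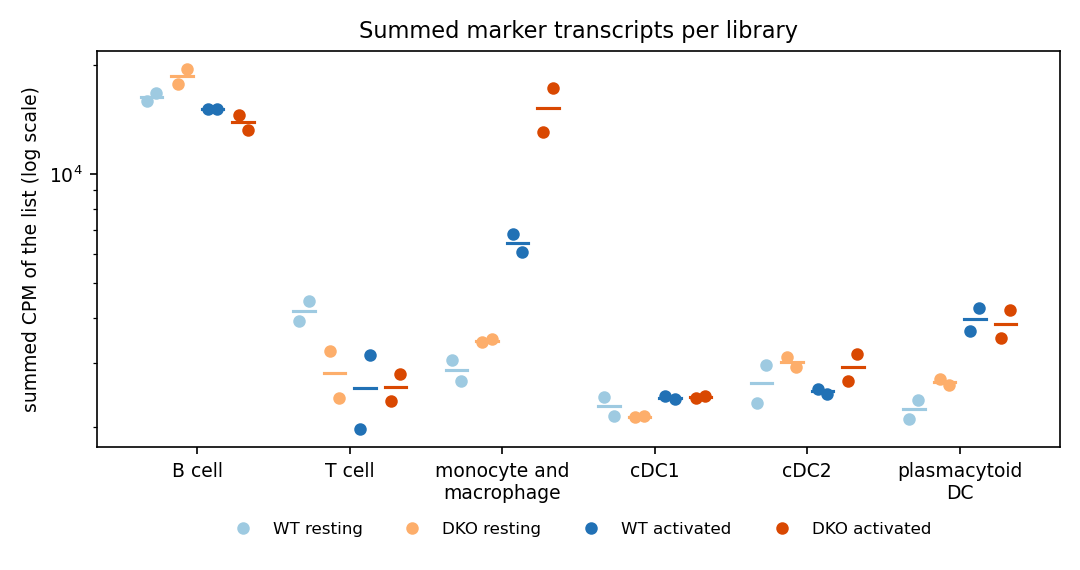
Summed TMM-scaled CPM (y axis, log scale) of the tested members of 6 marker lists (x axis) in each of the 8 libraries (dots), with the mean of each group as a line. The monocyte and macrophage list is highest in DKO activated libraries, at a mean of 15146 CPM, and the B cell list is the most abundant of the others shown in each group.

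Markers of DC subsets were called in both directions. Of 14 cDC1 markers 5 rose and 2 fell (camera adjusted p = 0.532), and Cd24a fell by 1.26 ± 0.21. Of 18 cDC2 markers 8 rose and 3 fell, with Ms4a6c up by 2.27 ± 0.26 and Csf1r, shared with macrophages, up by 1.78 ± 0.21 (camera adjusted p = 0.0420, adjusted p = 0.175 with an estimated correlation, 0.0713 without WT resting replicate 1 and 0.0976 without DKO resting replicate 2). Of 12 Langerhans and migratory DC markers 7 rose and 1 fell (camera adjusted p = 0.0859, and 0.0452 without WT activated replicate 2). Of 12 plasmacytoid DC markers 6 rose and 2 fell, with Bst2, also an interferon-stimulated gene, up by 1.90 ± 0.19 (camera adjusted p = 0.0422, adjusted p = 0.175 with an estimated correlation). That call ended without WT resting replicate 2 (adjusted p = 0.0507), DKO resting replicate 1 (0.0916) or WT activated replicate 2 (0.0653). Adjusted over the list alone these counts were 5 and 3, 8 and 3, 7 and 2, and 7 and 2. Of 32 adhesion molecules 11 fell and 6 rose (12 and 6 adjusted over the list alone), with Cd2 at −1.10 ± 0.14 and Itgb7 at −0.95 ± 0.15 (camera adjusted p = 0.0449, adjusted p = 0.222 with an estimated correlation). The adhesion call ended without WT resting replicate 1 (adjusted p = 0.0517), WT resting replicate 2 (0.0507), WT activated replicate 1 (0.0925) or DKO activated replicate 1 (0.144).

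Of 27 tested neighbours of Icam2 on chromosome 11, 11 fell and 2 rose (11 and 3 adjusted over the list alone), among them the B cell gene Cd79b at −0.58 ± 0.11 (camera adjusted p = 0.0420, adjusted p = 0.175 with an estimated correlation, 0.0507 without DKO resting replicate 1 and 0.0651 without WT activated replicate 2). Of 26 neighbours of Icam1 on chromosome 9, 7 rose and 5 fell (camera adjusted p = 0.920), with Cdkn2d, a cyclin-dependent kinase inhibitor gene, at −1.65 ± 0.24. Of 17 NK and ILC markers 4 rose and 1 fell (camera adjusted p = 0.826, with a median of −0.19 against a mean of 0.15), with Gzmb (granzyme B) up by 1.95 ± 0.30. Of 8 plasma cell markers 3 rose and 3 fell (camera adjusted p = 0.920), with Txndc5 at −1.76 ± 0.24. Of 5 stromal and endothelial markers 1 rose and 1 fell (camera adjusted p = 0.677). Adjusted over the list alone the counts of these last 4 lists were 7 and 5, 4 and 1, 3 and 3, and 2 and 1. Camera called 18 of 29 lists in this contrast, 13 up and 5 down, and 0 with an estimated correlation, whereas fry, added after seeing the data, called 20.

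The responses of WT and DKO cells were compared between separate libraries. In WT, 1237 genes were called, 727 higher and 510 lower, and the 5 with the smallest p were Cfp, Cfb, Vpreb3, Lyz1 and Cmah, an enzyme of sialic acid metabolism. In DKO, 1322 were called, 777 higher and 545 lower, led by Cfb, Cfp, Lyz2, C3 and Neurl3. Cfb rose by 3.52 ± 0.24 in WT and by 5.39 ± 0.28 in DKO, and C3, the central complement component, by 3.07 ± 0.31 in WT and by 3.96 ± 0.33 in DKO, with no interaction called by edgeR for either. A total of 460 genes rose in both genotypes, where independent lists would share 65.6, and 291 fell in both, where they would share 32.3. No gene was called in opposite directions (0). Of 1808 genes called in either genotype 96.8% had the same sign in both. Across all tested genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.686, and r lay between 0.545 and 0.648 when single libraries were left out. The WT count fell to 504, 748, 571 and 529 without WT resting replicate 1, WT resting replicate 2, WT activated replicate 1 and WT activated replicate 2, and was 806 with DESeq2. The DKO count fell to 820 without DKO resting replicate 1 and to 695 without DKO activated replicate 2, and was 857 with DESeq2.

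**Figure D3:**
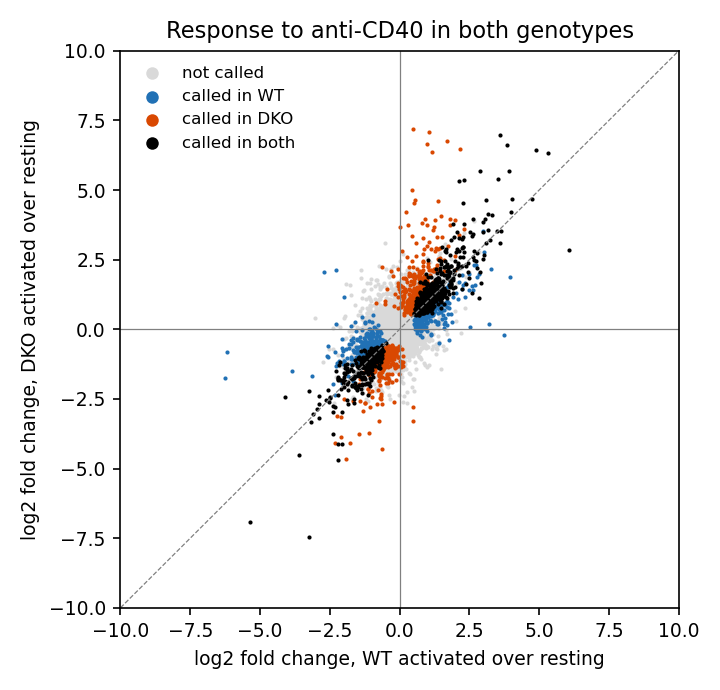
Log2 fold change on activation in DKO (y axis) against WT (x axis) for 8616 tested genes, coloured by the genotypes in which they were called. The dashed line marks equal change. Genes called in both genotypes lie in the upper right (460) and lower left (291), and 0 lie in the other corners.

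Few genes were called between genotypes. With both states averaged, edgeR called 18 genes, 12 higher and 6 lower in DKO, and 487 had an unadjusted p under 0.05. The largest rise was in BC018473, an antisense transcript on chromosome 11 (116752167 to 116759373), with 79 to 177 UMIs in DKO libraries and 0 to 3 in WT libraries. Its summed, depth-scaled ratio was 146 (exact 95% counting interval 62.3 to 453), and its fitted log2 change of 7.04 ± 0.35 depends on the prior count. St6galnac2, a sialyltransferase gene at 116675303 to 116694868, rose by 3.76 ± 0.28 (adjusted p = 6.79e-11), from 6 to 10 UMIs per WT library to 51 to 101 per DKO library. Cygb (cytoglobin), at 116645595 to 116654313 on chromosome 11, stood at 1.82 ± 0.34 (adjusted p = 0.00779) but lost its call without WT resting replicate 1 (1.74), DKO resting replicate 1 (1.72), DKO resting replicate 2 (1.95), WT activated replicate 2 (1.64), DKO activated replicate 2 (1.43) or both libraries of lowest depth (1.34), with adjusted p from 0.00126 to 0.310 over 14 alternatives. The macrophage genes Lyz2 and Apoe (apolipoprotein E) were 2.00-fold (adjusted p = 1.18e-05) and 1.71-fold (adjusted p = 6.41e-04) higher in DKO, and Eps8l1, related to an actin regulator, was 4.50-fold higher (adjusted p = 1.69e-04).

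Lower in DKO, besides Icam1, were Ifng at −2.42 ± 0.39 (adjusted p = 7.32e-04) and Xcl1 at −1.73 ± 0.31 (adjusted p = 0.00375), a cytokine and a chemokine of NK and T cells. The Ifng call ended without DKO resting replicate 2 (−1.95). The Xcl1 call ended in DESeq2 (−1.64) and without WT resting replicate 2 (−1.34), DKO resting replicate 2 (−1.22), WT activated replicate 2 (−1.44), DKO activated replicate 1 (−1.71) or DKO activated replicate 2 (−1.76). Jchain, a plasma cell gene, stood at −3.52 ± 0.70, but held 260 UMIs in WT resting replicate 1 and 0 in WT resting replicate 2, and its log2 change was 1.03 without the former. Its call held only without WT resting replicate 2 or WT activated replicate 2, 2 of the 8 fits that leave out a library. Igfbp7 at 1.06 ± 0.22, Cd63 at 1.03 ± 0.21 and Izumo1r at −1.15 ± 0.24 were also called, but each was called in only 1 of the 8 fits that leave out a library: without DKO activated replicate 1 for Cd63, without WT activated replicate 2 for Igfbp7 and without WT activated replicate 1 for Izumo1r. The count of 18 became 7 without DKO resting replicate 2, 9 without WT resting replicate 1, 11 without WT activated replicate 2, 9 without DKO activated replicate 2 and 11 without both libraries of lowest depth.

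**Figure D4:**
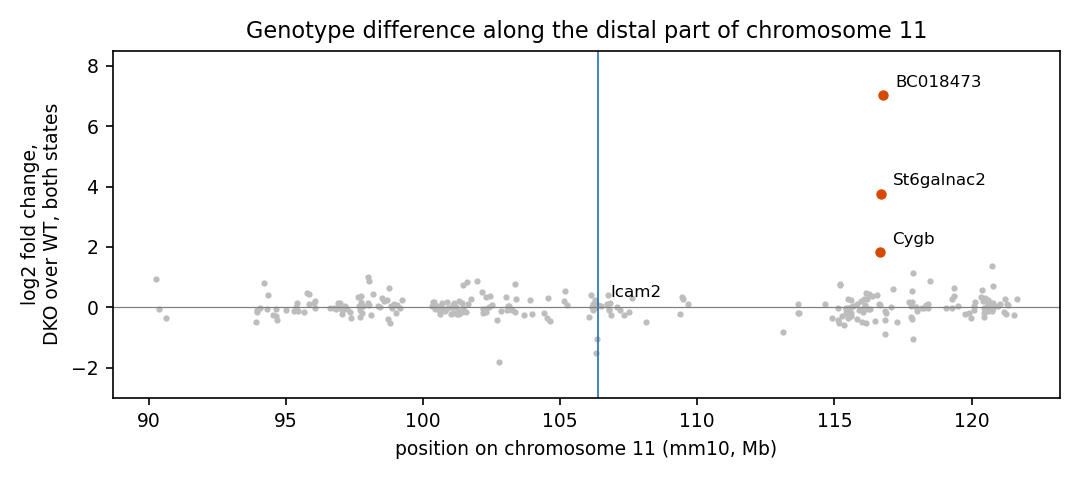
Log2 fold change of DKO over WT, averaged over both states (y axis), against gene midpoint on distal chromosome 11 (x axis, mm10, Mb). Called genes are orange and labelled, other tested genes are grey, and the vertical line marks Icam2; BC018473 (7.04), St6galnac2 (3.76) and Cygb (1.82) lie together.

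Between genotypes, the lists with the smallest camera p were markers of macrophages, T cells and NK cells. Of 20 macrophage markers 3 rose in DKO, Lyz2, Apoe and Lyz1 (the last called in 3 of the 8 fits that leave out a library, and not without WT resting replicate 1, either DKO resting library, WT activated replicate 2 or DKO activated replicate 1), with 12 higher and 1 lower adjusted over the list alone and a median of 0.63 (camera adjusted p = 6.63e-14, adjusted p = 0.157 with an estimated correlation). Of 24 T cell markers 0 were called (6 lower adjusted over the list alone), with a median of −0.31 (camera adjusted p = 2.07e-08, adjusted p = 0.255 with an estimated correlation). Their median was −0.63 at rest and 0.05 after activation, where they summed to 2567 ± 841 CPM in WT and 2585 ± 310 CPM in DKO libraries (SD, n = 2). Of 17 NK and ILC markers 1 fell, Xcl1 (3 lower adjusted over the list alone), with a median of −0.47 (camera adjusted p = 1.23e-05, adjusted p = 0.153 with an estimated correlation). Interferon-stimulated genes had 0 of 47 called, also adjusted over the list alone, with a median of −0.19 (camera adjusted p = 1.59e-04, adjusted p = 0.494 with an estimated correlation, 0.106 without DKO resting replicate 1 and 0.771 without DKO activated replicate 1). Among 32 adhesion molecules only Icam1 was called over all genes (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0348, adjusted p = 0.255 with an estimated correlation). Because Icam1 is itself deleted, the knockout contributes directly to the genotype calls of this list, which was not tested without it. The adhesion call ended without WT resting replicate 1 (adjusted p = 0.0633), DKO resting replicate 1 (0.0652), DKO resting replicate 2 (0.118), WT activated replicate 2 (0.232) or DKO activated replicate 1 (0.427). Itgal and Itgb2, the chains of LFA-1, stood at −0.13 ± 0.16 and 0.12 ± 0.15, with an adjusted p of 0.995 for both. 

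No member of the DC maturation, MHC class II or costimulation lists was called by edgeR (0 of 30, 0 of 20 and 0 of 17), and Cd40 stood at 0.02 ± 0.13 and Cd74 (invariant chain) at 0.12 ± 0.11. Adjusted over the list alone these lists had 3, 0 and 1 calls. The neighbours of Icam1 and Icam2, lists of 26 and 27 tested genes, had 0 called over all genes (1 and 0 adjusted over the list alone, camera adjusted p = 0.597 and 0.954). Among chemokines and their receptors Xcl1 was called (2 higher and 5 lower adjusted over the list alone, median −0.27, camera adjusted p = 0.0291, adjusted p = 0.255 with an estimated correlation), and Ccl22 stood at 0.61 ± 0.16 (edgeR adjusted p = 0.168). Immediate early genes had a median of −0.22 and 0 of 27 called (2 lower adjusted over the list alone, camera adjusted p = 9.04e-05, adjusted p = 0.153 with an estimated correlation). Markers of Langerhans cells, cDC2 and uptake receptors had 0 called (4, 1 and 1 higher adjusted over the list alone), with medians of 0.09, 0.24 and 0.16 (camera adjusted p = 0.00162, 0.00273 and 0.00551, adjusted p = 0.153, 0.153 and 0.226 with an estimated correlation). The lists of DC maturation, stromal and plasma cell markers were called near the threshold (camera adjusted p = 0.0479, 0.0291 and 0.0479, adjusted p = 0.494, 0.237 and 0.267 with an estimated correlation). Of these lists, that of chemokines lost its call without WT resting replicate 1, either DKO resting library, WT activated replicate 2 or DKO activated replicate 1 (adjusted p from 0.0732 to 0.380). That of DC maturation lost it without WT resting replicate 2, either DKO resting library, WT activated replicate 1 or DKO activated replicate 2 (0.0615 to 0.591). That of plasma cells lost it without WT resting replicate 1, either DKO resting library, either WT activated library or DKO activated replicate 1 (0.0501 to 0.557), and that of stromal cells without WT resting replicate 1, DKO resting replicate 1, WT activated replicate 2 or DKO activated replicate 1 (0.0732 to 0.405). That of uptake receptors lost it without WT resting replicate 1 (0.115) or DKO resting replicate 2 (0.253). Camera called 13 of 29 lists, 6 up and 7 down, against 0 with an estimated correlation and 0 by fry, and the count was 8 without WT resting replicate 1, DKO resting replicate 1, DKO resting replicate 2 or DKO activated replicate 1.

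At rest, 14 genes were called between genotypes, 5 higher and 9 lower in DKO. The 5 with the smallest p were BC018473, St6galnac2 (4.54 ± 0.40), Icam1 (−3.59 ± 0.34) and the chemokine genes Ccl4 and Ccl3. Ccl4 stood at 62.6 ± 14.8 CPM in WT resting and 4.18 ± 4.16 CPM in DKO resting libraries (edgeR adjusted p = 0.00154). Ccl3 had 0 and 1 UMIs in DKO resting libraries against 34.3 ± 0.751 CPM in WT resting libraries (edgeR adjusted p = 0.00856). The Ccl4 call ended without WT resting replicate 1 (−3.87), without DKO resting replicate 2 (−3.13) and in limma-voom. The Ccl3 call ended without those libraries (−5.14 and −7.73), without DKO resting replicate 1 (−4.61) and without both libraries of lowest depth (−4.62). It also ended in DESeq2 and in limma-voom. The value of −7.73 depends on the prior count, because the DKO resting library left in that fit held 0 Ccl3 UMIs. Adjusted p lay between 3.61e-04 and 0.272 for Ccl4 and between 0.00300 and 0.368 for Ccl3 over 15 alternatives each. Of 24 T cell markers 3 fell, Cd8a, Cd8b1 and Cd28 (9 adjusted over the list alone), with a median of −0.63 (camera adjusted p = 1.18e-19, adjusted p = 0.223 with an estimated correlation). These 3 genes lie outside the rule for named genes, were chosen after their values were seen, and were not called by DESeq2 (adjusted p = 0.0591, 0.166 and 0.414), while limma-voom called Cd8a and Cd8b1. Each lost its call without WT resting replicate 1 or either DKO resting library, Cd8b1 also without WT activated replicate 2, and Cd28 also without WT resting replicate 2 or either DKO activated library. DESeq2 called 4 genes and limma-voom 8. Single libraries left out gave 3 to 13 calls, with 3 without DKO resting replicate 2, 4 without WT resting replicate 1, 6 without DKO resting replicate 1, and 7 without DKO activated replicate 1 or DKO activated replicate 2.

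Other lists differed between genotypes at rest too, 11 of 29 in all by camera and 0 with an estimated correlation. Immediate early and dissociation stress genes, a list of sample quality, had a median of −0.27 and 0 of 27 called by edgeR (3 lower adjusted over the list alone, camera adjusted p = 1.98e-04, adjusted p = 0.223 with an estimated correlation). B cell and cDC2 markers had medians of 0.17 and 0.31 and 0 called, also adjusted over the list alone (camera adjusted p = 2.75e-04 and 0.0184, adjusted p = 0.223 for both with an estimated correlation). NK and ILC markers and cDC1 markers had medians of −0.26 and −0.29, with Xcl1 and Cd8a called lower (3 and 1 lower adjusted over the list alone, camera adjusted p = 0.0132 and 0.0137, adjusted p = 0.241 and 0.223 with an estimated correlation). Macrophage markers had a median of 0.35, a mean of 0.09 and 0 called (1 higher adjusted over the list alone, camera adjusted p = 0.0193, adjusted p = 0.729 with an estimated correlation). Chemokines (3 lower and 1 higher) and adhesion molecules (Icam1 lower) had medians of −0.45 and −0.22 (5 lower and 1 higher, and 1 lower, adjusted over the list alone, camera adjusted p = 0.00514 and 0.00125, adjusted p = 0.223 for both with an estimated correlation). Proliferation and interferon-stimulated genes had medians of −0.31 and −0.36 and 0 called (0 and 1 lower adjusted over the list alone, camera adjusted p = 0.0132 for both, adjusted p = 0.729 for both with an estimated correlation).

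After activation, 15 genes were called between genotypes, 12 higher and 3 lower in DKO. Icam1 fell by 3.48 ± 0.27, and BC018473, Lyz2 (1.58 ± 0.18), Apoe (1.32 ± 0.17) and St6galnac2 (2.99 ± 0.39) rose. Lyz2 reached 7166 ± 974 CPM in DKO and 2399 ± 493 CPM in WT activated libraries. Outside the rule for named genes, and chosen after their values were seen, Igfbp7 (1.75 ± 0.25, called in each of the 8 fits that leave out a library), Cfb (1.42 ± 0.20) and C3 (1.12 ± 0.24) were also called higher, and the ribosomal protein gene Rpl35 was called lower on 266 UMIs in WT activated replicate 2 alone. The Cfb call ended without WT activated replicate 2, and the C3 call without any single activated library. Of 20 macrophage markers 2 rose (15 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 1.86e-22, adjusted p = 0.123 with an estimated correlation). The count of 15 became 6 without WT activated replicate 2, 36 without DKO activated replicate 1 and 8 without DKO activated replicate 2, and was 23 with limma-voom.

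Camera called 9 of 29 lists between genotypes after activation, and 0 with an estimated correlation. Apart from the macrophage list, these had 0 genes called by edgeR over all genes. Uptake receptors and markers of Langerhans cells, cDC2 and stromal cells had medians of 0.41, 0.35, 0.24 and 0.12, with 5, 2, 3 and 1 higher and 1 cDC2 marker lower adjusted over the list alone (camera adjusted p = 1.40e-05, 4.43e-04, 0.0325 and 0.0224, adjusted p = 0.123, 0.123, 0.199 and 0.199 with an estimated correlation). NK and ILC markers, NF-kB targets, interferon-stimulated genes and immediate early and dissociation stress genes, a list of sample quality, had medians of −0.61, −0.18, −0.05 and −0.20, with 0, 1, 0 and 0 lower adjusted over the list alone (camera adjusted p = 0.00254, 0.0154, 0.00617 and 0.0240, adjusted p = 0.199, 0.199, 0.771 and 0.199 with an estimated correlation).

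The interaction asks whether the response to the antibody differs between genotypes. No gene was called by edgeR (0 of 8616), DESeq2 (0) or limma-voom (0), and 397 had an unadjusted p under 0.05 in edgeR, with a smallest adjusted p of 0.156. Icam1 had an interaction of 0.11 ± 0.45 and Icam2 of 0.59 ± 0.37. Between 0 and 2 genes were called when single libraries were left out, 1 without WT resting replicate 2, 1 without WT activated replicate 1 and 2 without DKO activated replicate 2. With a median SE of 0.52, many differences between the responses were not detectable at this depth and number of libraries. The simulated interaction recovered 11% of changes at 2-fold and 55% at 4-fold. The absence of called genes therefore does not show that the responses were alike. The genotype log2 fold changes at rest and after activation had a Pearson r of 0.0962 across genes, most of them not called in either state. Of 25 genes called in either state, picked by their calls in the same data, 80% had the same sign, with r at 0.761. In both states 3 genes were called higher and 1 lower.

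In the authors' deposited table, 811 genes passed an adjusted p of 0.05 for activation in WT and 892 in DKO, of which 804 and 891 were also called here. For genotype, the authors' deposited table called 12 genes after activation and 5 at rest, and 12 and 5 of these were called here. The authors' deposited table gives Icam1 a log2 fold change of −3.16 after activation and −2.82 at rest, on its own scale.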

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

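The weighing of the chromosome 11 genes and of macrophage transcripts rests on tests chosen after the results were seen, as do the counts over other splits of the libraries.

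A difference in response between the genotypes, by camera on the interaction, singled out 7 gene lists, although no single gene had an interaction called by edgeR (0 called, 397 at an unadjusted p under 0.05, 0 in DESeq2 and 0 in limma-voom). Values are the median log2 change of DKO activation minus WT activation. T cell markers stood at 0.70 (camera adjusted p = 1.06e-11, 0.473 with an estimated correlation), with activation medians of −0.83 in WT and −0.07 in DKO. Monocyte and macrophage markers stood at 0.52 (5.22e-04, 0.476), with 1.71 in WT and 2.28 in DKO. Proliferation genes stood at 1.02 (7.58e-04, 0.528), with 0.83 in WT and 1.56 in DKO. Chemokines and their receptors stood at 1.02 (0.0172, 0.473), with 0.48 in WT and 1.99 in DKO. B cell markers stood at −0.29 (7.58e-04, 0.473), with −0.67 in WT and −0.74 in DKO. Adhesion molecules stood at 0.10 (0.0456, 0.473), with −0.50 in WT and −0.16 in DKO. Neighbours of Icam1 on chromosome 9 stood at −0.31 (0.0456, 0.476), with 0.17 in WT and −0.13 in DKO. All 7 calls were lost with an estimated correlation, and the unadjusted fry p was 0.111 or more in each. The estimated correlation left 0 lists called in every contrast, so that loss does not tell these 7 lists from others. The calls were made only by camera with the preset correlation.

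BC018473, St6galnac2 and Cygb, 3 of 18 genes called between genotypes, lie together on chromosome 11, with 97.9 kb between the outer genes, 10.3 to 10.4 Mb from Icam2. A difference in depth is argued against: the lowest DKO count of BC018473 was 79 UMIs and the highest WT count 3, although the shallowest libraries are DKO. A candidate explanation is sequence of the donor strain kept around the deleted Icam2, and genes within 15 Mb of Icam2 other than these had an odds ratio of 1.60 for an unadjusted genotype p under 0.05 (95% interval 0.984 to 2.48, Fisher's exact p = 0.0425, 0.0849 adjusted over 2 windows). The window around Icam1, the other deleted gene, had an odds ratio of 1.02 (0.321 to 2.49, Fisher's exact p = 0.818). The called gene Izumo1r lies in that window and was likewise left out of the test. The strain of origin is not given in the sources used here and the genotype is confounded with it, so this cannot be told apart from an effect of losing ICAM-1 and ICAM-2, which stays untested.

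Of 20 macrophage markers 2, Lyz2 and Apoe, were called higher in activated DKO than in activated WT libraries (edgeR), with a median of 0.79 over the list (camera adjusted p = 1.86e-22, adjusted p = 0.123 with an estimated correlation). Lyz2 went from 2399 CPM in WT to 7166 CPM in DKO and Apoe from 1557 to 3894 CPM, and the list summed to 6445 and 15146 CPM. A lower share of the main cell type would raise markers of every other cell type alike. The upper quartile of T cell markers was 0.13 and the lower quartile of macrophage markers 0.55, so these did not rise alike. The T cell median was 0.05. NK and ILC markers had a median of −0.61 and an upper quartile of −0.10, with 4 of 17 above 0. For these lists, the values argue against a lower share of the main cell type as the only difference between activated libraries. T cell markers are no neutral reference across states, however. Activation moved them by a median of 0.70 more in DKO than in WT, against 0.52 for macrophage markers. A lower share combined with other shifts in the cell mix was not tested. More macrophages or their RNA among the sorted cells, and a difference between the genotypes in the cells' own expression, both predict higher markers, and no test here separates them. The gate on CD11c and MHC-II would not remove macrophages that carry both.

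B cell transcripts were abundant in every library: Cd79b stood at 2415 to 4392 CPM, against 16.1 to 43.0 CPM for Itgax, which encodes CD11c, and 14 of 16 tested B cell markers held by no other list were at 50 CPM or more in every library. Of plasmacytoid DC markers, Siglech stood at 28.6 CPM or less in each library, while the 12 tested members of that list, some of them shared with the B cell list, summed to 2245 ± 191 CPM in WT resting and 3968 ± 419 CPM in WT activated libraries (SD, n = 2). These values do not settle which cells the transcripts came from.

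Other splits of the 8 libraries into 4 and 4, each fitted beside the factor not tested, numbered 34 with the real one. For activation only 1 split, the real one, called as many genes (2563, against at most 0 elsewhere) and lists (15, against at most 12). The other splits leave the activation effect in the residual spread, which lowers their counts of genes, so these counts do not measure chance alone. For genotype only 1 split called as many genes (17, against at most 6). However, 3 splits called as many lists as the real 11 (at most 12), so chance is not excluded for the lists. The other splits with the most genes and lists set 3 activated libraries beside 1 resting library, unlike the real split. Other splits that divide each state evenly called at most 2 genes and at most 10 lists, but are too few to exclude chance. The libraries of a group may not be separate animals, so no count of splits excludes chance between animals.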

How the results depend on the processing

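Fits without both libraries of lowest depth and fry were chosen after the results were seen. No paired analysis was possible because the labels number the libraries 1 to 8 and name no animal, day or number shared between groups. Without single libraries, where a lone library is assumed to vary like the other groups, calls ran from 1861 to 2373 for activation in both genotypes, 504 to 1388 in WT, 695 to 1192 in DKO, 7 to 14 for genotype in both states, 3 to 13 at rest, 6 to 36 after activation and 0 to 2 for the interaction. Lists ran from 15 to 18 for activation and 8 to 17 for genotype, and r between the responses from 0.545 to 0.648. Jchain between genotypes ran from −5.26 to 1.03 (reversed without WT resting replicate 1). With genes filtered anew in each such fit, which was tried first, the ranges were 1887 to 2402, 505 to 1407, 703 to 1229, 9 to 19, 3 to 15, 6 to 38 and 0 to 6, with r from 0.487 to 0.606. Without both libraries of lowest depth the counts were 553 for activation in DKO, 11 for genotype in both states, 6 at rest, 8 after activation and 2 for the interaction, with r at 0.610. DESeq2 gave 806 for activation in WT, 857 in DKO and 4 for genotype at rest, limma-voom 1871 for activation in WT, 8 for genotype at rest and 23 after activation, and only the 4 libraries compared 9 at rest. Without a filter r was 0.529. Lists numbered 0 for activation and 0 for genotype with an estimated correlation, and 0 for genotype by fry. Beyond the smaller number of libraries, the cause was not tested.

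Each value counted here is a named gene in a given comparison and fit. Without a single library, 1642 such values kept direction and side of the threshold, 69 lost their call and 1 reversed. These counts pool activation genes picked by p in the same data with genes that were not called, so they do not describe the genotype calls. The call was lost for 8 values with DESeq2, 6 with limma-voom, 1 with the stricter filter and 2 in the 4-library fits. It was lost for 11 without both libraries of lowest depth, and for 0 with DESeq2 size factors or no filter. Counted likewise for lists, 45 values lost their call and 14 gained it without a single library. Depth limits genes near the floor of 2.11 to 7.16 CPM. In the interaction 11% of simulated 2-fold changes and 55% of 4-fold changes were recovered, and the simulation does not separate depth from the number of libraries.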

Other observations

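The following genes and levels were chosen after their values were seen. Of genes typical of conventional DCs, Flt3 had 3 to 44 UMIs per library, Zbtb46 0 to 8, Xcr1 0 to 8 and Cd209a 0 to 9, while Irf8, which B cells also express, stood at 487 to 892 CPM. Group means of the summed lists were 2132 to 2422 CPM for cDC1 markers and 2508 to 3024 CPM for cDC2 markers, sums to which genes that other cells also express contribute much, such as Irf8 (580 CPM in WT resting libraries) and S100a4 (1307 CPM). MHC class II transcripts were abundant, with H2-Aa at 10096 to 14040 CPM and Cd74 at 11113 to 16130 CPM, and Cd86 stood at 28.3 to 66.8 CPM. Among B cell genes, Fcer2a (CD23) rose by 0.94 (log2) with activation, and Cd22 and Fcmr fell by 0.88 and 1.22.

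Ifng stood at 39.3 ± 14.0 CPM in WT resting, 10.2 ± 9.11 in DKO resting, 63.0 ± 30.2 in WT activated and 11 ± 4.67 in DKO activated libraries (SD, n = 2). Kdm5d, on chromosome Y, had 3 to 23 UMIs in DKO libraries and 0 to 2 in WT libraries, a summed, depth-scaled ratio of 11.9 (exact 95% counting interval 5.05 to 34.0). It was among the 18 genes called between genotypes (3.38 ± 0.68, edgeR adjusted p = 0.0159), but DESeq2 did not call it (adjusted p = 0.0580). The edgeR call held in only 2 of the 8 fits that leave out a library. The WT counts lie below the floor of 3 UMIs, so the fitted log2 change depends on the prior count. The sex of donors and recipients is not given in the sources used here, so whether it differs between the genotypes is not known.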
